A study of Homo sapiens with 12 samples.

How the data were processed

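Poly-A enriched RNA was sequenced from 2 human breast cancer cell lines, MDA-MB-231 and HCC1937, which both come from triple-negative tumours, a class that lacks the estrogen and progesterone receptors and HER2 amplification. Each line was cultured for 72 h without extract (control) or with an aqueous extract of Kalanchoe pinnata, a succulent plant used in traditional medicine, and each of the 4 groups held 3 libraries. MDA-MB-231 was grown in DMEM and received 140 µg/mL of extract, while HCC1937 was grown in RPMI and received 66 µg/mL, so line, medium and concentration cannot be separated. The libraries keep the numbers of the deposited table: E1 to E3 are MDA-MB-231 controls, E7 to E9 MDA-MB-231 with extract, E25 to E27 HCC1937 controls and E31 to E33 HCC1937 with extract. Groups were taken from the sample titles. Per the labels, messenger RNA was captured on poly-T beads, although the kit named there is one for total RNA. The labels do not say that the replicates of a group were separate cultures, so every p-value measures the spread between these libraries, which may be technical.

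The authors checked reads with FastQC 0.12.1, trimmed them with fastp 0.23.4 and quantified them with Salmon 1.10.3 on GRCh38, and their own test, DESeq2, ran in R 4.4.1. The deposited table holds expected counts, that is the estimated number of reads per gene, with no scaling for depth. The annotation release behind the Salmon index, the step that summed transcripts to genes and the design of the authors' test are not given in the sources used here. The table has 19517 genes, of which 1 has no symbol and no reads, and 99.4% are protein-coding. Of all values, 52.8% were not whole numbers, and all were rounded to whole counts, which moved no value by more than 0.5. Library totals ran from 16170545 to 31337431 counts. For a single library, 3 counts correspond to 0.0990 to 0.213 CPM (counts scaled to a common library size). A fold against a group with no reads in any library was computed against 3 counts over the group and is a lower bound. Such floors cover counting error only.

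Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 4 groups, which left 14133 of the 19516 genes with a symbol. Libraries were scaled by TMM, a single model with 4 groups and no intercept was fitted to all 12 libraries, and contrasts were tested with the quasi-likelihood F test. Adjusted p-values are Benjamini-Hochberg over all genes tested, and a gene is said to have risen or fallen at an adjusted p under 0.05. TMM takes most genes as unchanged, and no measure of RNA per cell was used. So rises and falls are relative to the other genes of a library, and a change in total messenger RNA would not show. Folds carry their standard error (SE) and CPM values their standard deviation (SD) over the 3 libraries of a group. Comparisons were extract against control in each line, the difference of these effects between the lines (HCC1937 minus MDA-MB-231), and HCC1937 controls against MDA-MB-231 controls. Overlap of the calls in both lines was compared with the number expected from the margins.

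Gene lists for signalling, stress, metabolism, cell cycle and cell types were fixed before the data were examined, together with the comparisons, the tests, the rule for naming genes and most of the alternatives. Of these, 38 lists had at least 5 tested genes and were tested per comparison with camera in limma 3.58.1 on log2 CPM with a prior count of 2, at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. Camera asks whether a list moved relative to the other genes. An estimated correlation was used beside it, as was fry, which asks whether the genes of a list moved at all. Genes named in the text are the 4 genes in the title of the series, the 8 largest rises and 8 largest falls per line among called genes with a mean of at least 5 CPM over the line and groups that did not overlap, the 4 largest differences between the lines in each direction, the members of each described list with the smallest p, housekeeping genes and genes that tell the lines apart. Which lists are described was settled after their results were seen. A few of the genes that this rule names and some of the lists are not reported here.

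Transcript length, GC content and genomic span were taken from GENCODE release 29 for 14065 of the tested genes (99.5%), using the longest protein-coding transcript of a gene. A length and GC offset was fitted per library as a smooth surface with mgcv 1.9.3 and passed to edgeR. Its form was revised on simulated data after a first form left many false calls. In counts simulated from the control means and the real library sizes, with 100 genes changed 2-fold, the test recovered 98% of these in MDA-MB-231 and 100% in HCC1937, with 7.02% and 7.08% false among all calls. The simulated spread was estimated without the MDA-MB-231 extract libraries. Their biological coefficient of variation was 0.296, against 0.0409 to 0.0449 in the other groups. So the values for MDA-MB-231 hold for a smaller spread than the real one. When a trend linear in GC content and log2 length was simulated as well, false calls made up 98.2% and 98.1% without the offset and 13.7% and 19.6% with it.

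Alternatives were DESeq2's size factors and upper quartile scaling in edgeR, DESeq2 1.42.0, limma-voom, no count filter, a filter of at least 50 counts in at least 3 libraries, a log2 fold change of at least 1, only the 6 libraries compared, the offset, and each library left out in turn. The offset with E7 left out, the offset with an estimated correlation for lists, lists for the difference without genes that lack a fold in a line, the offset for the overlap, and counts without genes at under 1% of the other line's level were added after seeing the data. Other splits of the libraries into groups of the same sizes were fitted as well. The genes compared for carried-over reads were selected by a rule widened after a first form left 5 genes. No column of the table was left out. Genes with near-identical copies, such as RGPD6, KRTAP2-3, CCDC144A, ZNF117, MAGEA3, MAGEA12, RPL39L, HSPA1B and the mitochondrial genes ND1 and CYTB, have uncertain counts, since reads can be shared with the copies.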

Results

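The data are estimated read counts per gene for 12 libraries in 4 groups of 3: MDA-MB-231 and HCC1937 cells, each with and without 72 h of Kalanchoe pinnata extract. The control libraries of MDA-MB-231 held 18134958 (E1), 16170545 (E2) and 18949210 (E3) counts, and its extract libraries 18447464 (E7), 26420547 (E8) and 22625305 (E9). HCC1937 controls held 22297014 (E25), 26212277 (E26) and 24540968 (E27) counts, and HCC1937 extract libraries 29126179 (E31), 29246488 (E32) and 31337431 (E33). Extract libraries had reads in fewer genes. Group means were 14908 genes in MDA-MB-231 controls against 14411 with extract, and 15062 in HCC1937 controls against 14115 with extract. Mitochondrial genes took 2.81 ± 0.0582% of counts in MDA-MB-231 controls and 6.72 ± 3.49% with extract (SD, n = 3). This spread came from E7, at 10.7% beside 4.63% in E8 and 4.78% in E9. In HCC1937 they took 3.62 ± 0.0780% without and 3.87 ± 0.106% with extract. E7 also stood apart across genes, with a Spearman correlation of 0.967 to E8 and 0.966 to E9, where every other pair of replicates reached at least 0.9968. The biological coefficient of variation was 0.296 in the MDA-MB-231 extract group and 0.0409 to 0.0449 in the other groups.

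With extract, long transcripts and transcripts poor in GC were lower in both lines, and short GC-rich ones were higher. The median log2 fold change of 508 genes with transcripts over 8 kb and at most 42% GC was -1.74 in MDA-MB-231 and -1.97 in HCC1937. Among 1039 genes with transcripts of at most 2 kb and over 58% GC it was 0.79 and 0.88. Length and GC content accounted for 43.9% of the variance of fold changes across genes in MDA-MB-231 and 54.7% in HCC1937, where genes are not independent replicates. The title genes and the medians of the lists described in each line are therefore given with the length and GC offset as well, and the medians of called lists in MDA-MB-231 also without E7. For the largest changes, direction and call are given with the offset, and values for some of them. Single genes of a list are given without the offset, except where it ended or turned their call.

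**Figure D1:**
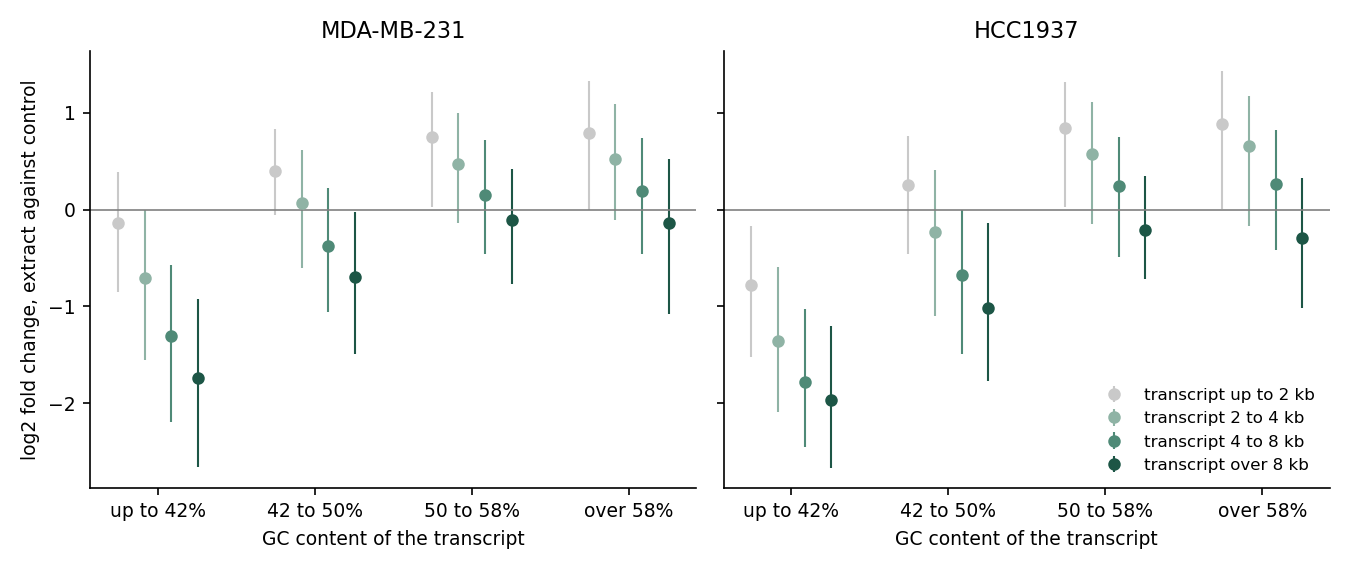
Median log2 fold change with extract in each line (vertical axis; bars span the quartiles of genes) by GC content in percent and by transcript length, in bins of at least 82 genes. In both lines the medians fall with transcript length and rise with GC content, except that for transcripts over 8 kb they are lower in the bin over 58% GC than in the bin of 50 to 58%.

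The title of the series names JAK2, ROCK1, ROCK2 and PIK3CA as lowered by the extract, and the comparison of extract with control in each line asks whether their transcripts were. All 4 fell in both lines, and each extract library lay below each control library of its line. ROCK1 (Entrez 6093) is a kinase that drives actomyosin contraction downstream of RHOA, encoded on GRCh38 chromosome 18 from 20946906 to 21111851. It went from 66.9 ± 1.92 to 3.58 ± 1.11 CPM in MDA-MB-231 and from 68.3 ± 4.24 to 7.55 ± 1.18 CPM in HCC1937 (SD, n = 3). Its log2 fold changes were -4.26 ± 0.19 (SE; 19.1-fold lower, edgeR adjusted p = 6.45e-09) and -3.18 ± 0.18 (9.04-fold lower, adjusted p = 2.22e-08). ROCK2 (Entrez 9475; chromosome 2, 11179761 to 11348330), the related kinase, went from 37.7 ± 0.538 to 2.78 ± 0.695 CPM and from 82.6 ± 8.40 to 9.70 ± 1.36 CPM. Its log2 fold changes were -3.73 ± 0.17 (adjusted p = 6.2e-09) and -3.09 ± 0.15 (adjusted p = 8.68e-09). PIK3CA (Entrez 5290; chromosome 3, 179148114 to 179240093) encodes the catalytic subunit of phosphoinositide 3-kinase alpha. It went from 42 ± 1.39 to 3.95 ± 1.1 CPM and from 31.6 ± 2.16 to 5.54 ± 0.358 CPM, with log2 fold changes of -3.38 ± 0.16 (adjusted p = 8.46e-09) and -2.51 ± 0.15 (adjusted p = 3.79e-08). JAK2 (Entrez 3717; chromosome 9, 4984390 to 5128183), a tyrosine kinase of cytokine receptors, was scarce. It had 393 reads over the 3 control libraries and 73 over the extract libraries of MDA-MB-231, and 315 and 38 in HCC1937. JAK2 went from 6.59 ± 0.645 to 1.12 ± 0.285 CPM and from 3.68 ± 0.758 to 0.497 ± 0.228 CPM. Its fold changes were -2.52 ± 0.28 (adjusted p = 9.97e-06) and -2.87 ± 0.31 (adjusted p = 5.39e-06).

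Adjusted over the list alone, all 4 genes passed in both lines as well, with 1.97e-06 in MDA-MB-231 and 1.32e-06 in HCC1937 for JAK2, the highest of the 4. These genes come from the title of the series that holds these samples, so their fall is not independent evidence of direction. Their transcripts are 5285 to 9484 nt long with 34.8% to 40.5% GC, a class that fell as a whole. Among the 200 genes nearest to each in length and GC, ROCK1 stood at percentile 2 in MDA-MB-231 and 5.5 in HCC1937, ROCK2 at 6 and 5.5, JAK2 at 21 and 10, and PIK3CA at 13 and 47.5. With the offset the log2 fold changes in MDA-MB-231 were -2.75 for ROCK1, -2.20 for ROCK2, -1.27 for JAK2 and -1.16 for PIK3CA, and in HCC1937 -1.46, -1.34, -1.30 and -0.12 in that order. PIK3CA in HCC1937 was then no longer called (-0.12 ± 0.12, adjusted p = 0.399, the highest of its 21 alternatives, which start at 4.52e-81). The other 7 falls were called under every alternative, with adjusted p of at most 0.00199.

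**Figure D2:**
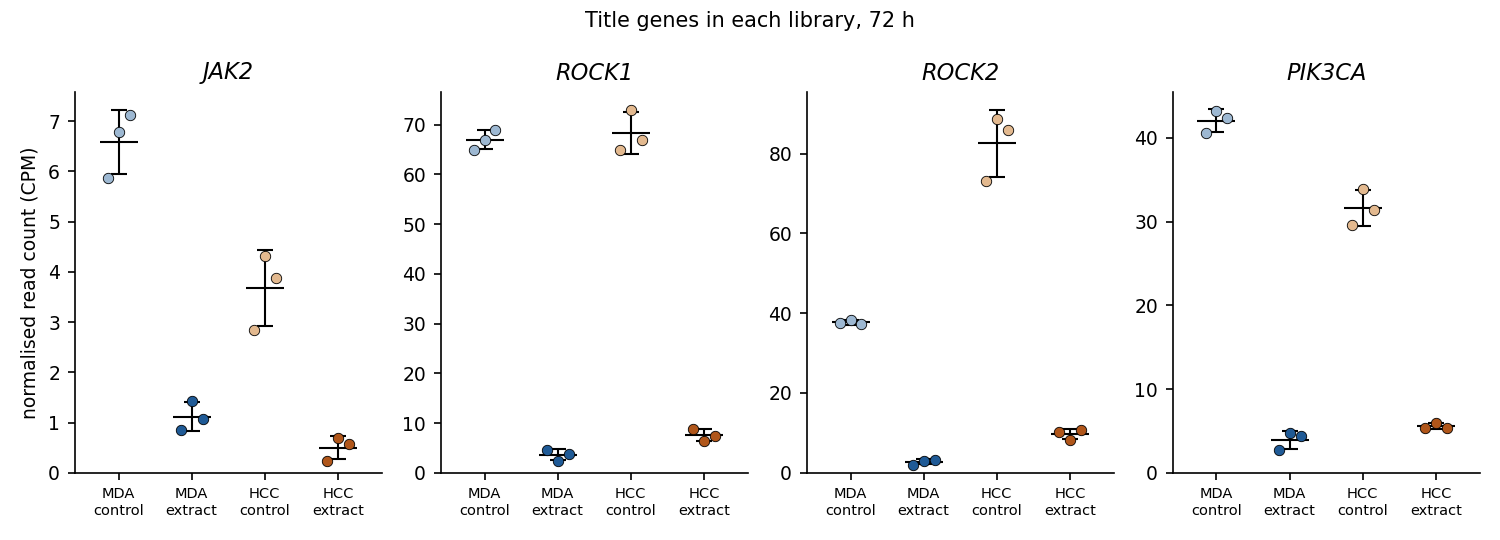
Level of JAK2, ROCK1, ROCK2 and PIK3CA in CPM (vertical axis) in each library (points), with the mean and SD of the 3 libraries of each of the 4 groups (bars). For all 4 genes, each extract library lies below each control library of the same line.

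Extract against control in MDA-MB-231, at 140 µg/mL, raised CHAC1, an enzyme that breaks down glutathione. It lowered CCDC88A (girdin), an actin-binding protein of migrating cells, and ATRX, a chromatin remodeller. CHAC1 rose 11.3-fold, from 4.16 to 47.0 CPM (log2 fold change 3.50 ± 0.12, adjusted p = 1.28e-09). CCDC88A went from 90.4 to 3.39 CPM (-4.70 ± 0.19, adjusted p = 3.27e-09) and ATRX from 87.2 to 3.31 CPM (-4.67 ± 0.19, adjusted p = 3.27e-09). Other large rises were KRTAP2-3, a hair keratin-associated protein (5.08), HPS6, part of a complex that forms lysosome-related organelles (4.19), and the mitochondrial RNA helicase DDX28 (3.95). LCMT2, which modifies transfer RNA (3.67), ZBTB9 (3.57), and the mitochondrially encoded ND1 (3.98, or 3.06 without E7) and CYTB (3.82, or 3.01 without E7) completed them. Large falls were also seen for ANKRD12 (-5.02), the centrosomal CEP152 (-4.79), ANKRD26 (-4.70), the DNA break repair gene RAD50 (-4.63) and the lipid transfer gene VPS13A (-4.54). RGPD6 fell as well (-5.48 ± 1.19, adjusted p = 0.00159), but its value was -7.28 without E7 and -4.83 without E9, and DESeq2 gave it no adjusted p. The transcripts of the 8 falls are 5635 to 15320 nt long with 35.6% to 41.4% GC. With the offset all 16 genes kept their direction and their call, among them CHAC1 at 2.66, CCDC88A at -2.80 and ATRX at -2.61. In all, 4667 genes rose, 4636 fell and 4830 did not pass, and 2112 rose and 2968 fell with a log2 fold change of at least 1. With the offset 3203 of the rises and 3170 of the falls kept their direction and call, and 702 genes were called the opposite way.

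Genes of the amino acid and integrated stress response under ATF4 rose together in MDA-MB-231. Of 23 measured, 17 rose, 2 fell and 4 did not pass, with the same counts adjusted over the list alone. Their median log2 fold change was 0.96 (camera adjusted p = 0.00121), 0.65 with the offset and 1.02 without E7. Besides CHAC1, the pseudokinase TRIB3 rose from 47.0 to 129 CPM (1.46, adjusted p = 5.7e-09) and the serine pathway enzyme SHMT2 from 308 to 763 CPM (1.31, adjusted p = 1.39e-08). SLC7A11, the cystine importer of this list, fell (-1.98), but was at 0.20 with the offset (adjusted p = 0.0207, the highest of 21 alternatives from 1.28e-76). Heat shock chaperones went the other way: of 16, 12 fell, 1 rose and 3 did not pass, again the same adjusted over the list alone. Chaperones had a median of -2.09 (camera adjusted p = 0.00121), -1.27 with the offset and -1.95 without E7. HSP90AA1, the inducible cytosolic HSP90, went from 4391 to 492 CPM (-3.16 ± 0.08, adjusted p = 2.91e-10). The co-chaperone DNAJB1 went from 1827 to 233 CPM (-2.97 ± 0.10, adjusted p = 9.66e-10) and HSPH1, a partner of HSP70, from 524 to 47.0 CPM (-3.48 ± 0.09, adjusted p = 2.91e-10).

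DNA replication genes of S phase were higher with extract in MDA-MB-231: 18 of 24 rose, 4 fell and 2 did not pass, the same adjusted over the list alone. S phase genes had a median of 0.82 (camera adjusted p = 0.00277), 0.41 with the offset and 0.84 without E7. The flap endonuclease FEN1 rose from 36.1 to 136 CPM (1.91, adjusted p = 2.61e-09) and the origin licensing factor CDC6 from 45.7 to 119 CPM (1.38, adjusted p = 8.31e-08). CLSPN, the checkpoint adaptor claspin of the same list, fell (-2.26, adjusted p = 2.65e-07). Mitosis genes were not called as a list, with 7 rising, 14 falling and 4 not passing, the same adjusted over the list alone (median -0.92, camera adjusted p = 0.0883). The kinetochore protein CENPF (-4.31 ± 0.12, adjusted p = 4.41e-10) and the spindle protein DLGAP5 (-3.37, adjusted p = 7.53e-10) fell. The mitosis median with the offset was -0.61 and camera called it (adjusted p = 0.0332, in a range of 1.21e-10 to 0.269 over 18 alternatives, the highest with an estimated correlation). With the offset and an estimated correlation together it was not called (adjusted p = 0.405). The calls for ATF4 targets, chaperones and S phase were the 3 that held with an estimated correlation (adjusted p = 0.0435 for each). With the offset as well none of these 3 held (adjusted p = 0.134, 0.134 and 0.136 in that order).

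Lipid synthesis genes fell in MDA-MB-231. Of 23 genes of cholesterol synthesis and uptake, 12 fell, 4 rose and 7 did not pass, the same adjusted over the list alone. Cholesterol genes had a median of -0.56 (camera adjusted p = 0.0252; adjusted p = 0.148 with an estimated correlation and 0.0681 without E7). HMGCS1, which opens the mevalonate pathway, went from 390 to 59.9 CPM (-2.70, adjusted p = 2.67e-09) and INSIG1, a feedback sensor of sterols, from 412 to 86.0 CPM (-2.26, adjusted p = 4.94e-10). The sterol oxidase MSMO1 fell as well (-1.95, adjusted p = 2.27e-09). Of 14 fatty acid genes, 10 fell, none rose and 4 did not pass, also adjusted over the list alone. Fatty acid genes had a median of -0.73 (camera adjusted p = 0.00505; adjusted p = 0.848 with an estimated correlation). ACSL3, which activates long-chain fatty acids (-2.09, adjusted p = 7.75e-10), the elongase ELOVL6 (-2.19, adjusted p = 1.78e-08) and the acetate-activating ACSS2 (-1.56, adjusted p = 2.03e-08) had the smallest p. With the offset the medians were -0.78 for cholesterol and -0.68 for fatty acids, and without E7 -0.52 and -0.65. Medians below 0 were not particular to this line. In HCC1937 the medians were -0.46 for cholesterol and -0.87 for fatty acid genes, neither called. Fatty acid genes were not called for the difference between the lines (median -0.024, camera adjusted p = 0.418). Cholesterol genes were called higher in HCC1937 for this difference (median -0.015, camera adjusted p = 0.0470), a call that leaving out 1 library could end.

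Targets of the YAP and TEAD factors, which respond to cell tension, rose for 10 of 16, fell for 3 and did not pass for 3 in MDA-MB-231, the same adjusted over the list alone. YAP and TEAD targets had a median of 1.28, or 0.92 with the offset and 1.36 without E7 (camera adjusted p = 0.0252; adjusted p = 0.848 with an estimated correlation). Tissue factor F3 rose from 24.9 to 155 CPM (2.64, adjusted p = 4.41e-10) and the matricellular protein CCN2 from 110 to 432 CPM (1.98, adjusted p = 4.47e-09). The LIM protein AJUBA rose by 2.06 on the log2 scale (adjusted p = 7.61e-10). The call of this list was lost without E8 (adjusted p = 0.0585) and without E9 (adjusted p = 0.0619).

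Mitochondrial and ribosomal transcripts were higher with extract in MDA-MB-231, and the size of their rise depended on E7. Of 13 mitochondrially encoded genes 11 rose, none fell and 2 did not pass, also adjusted over the list alone. Mitochondrially encoded genes had a median of 1.88, 1.26 without E7 and 1.33 with the offset (camera adjusted p = 0.00337; adjusted p = 0.848 with an estimated correlation). ND5 of complex I was among them (1.42, adjusted p = 1.05e-06). Of 29 nuclear genes of oxidative phosphorylation 21 rose, 1 fell and 7 did not pass, also adjusted over the list alone. Respiratory genes had a median of 0.80, or 0.34 without E7 (camera adjusted p = 0.00591; adjusted p = 0.865 with an estimated correlation). With the offset this median was 0.14 and the call ended (camera adjusted p = 0.602). Cytochrome c1, CYC1 (1.13, adjusted p = 5.87e-06), was at 0.16 with the offset and ATP5F1B, a subunit of ATP synthase (0.73, adjusted p = 5.25e-05), at 0.07, neither called. NDUFB7 of complex I rose as well (1.61, adjusted p = 0.000464). Of 35 ribosomal proteins 24 rose, 0 fell and 11 did not pass, or 27 rose adjusted over the list alone. Ribosomal proteins had a median of 0.81, or 0.20 without E7 (camera adjusted p = 0.00704; adjusted p = 0.865 with an estimated correlation). RPL8 (1.26, adjusted p = 0.000176) and RPS3 (0.88, adjusted p = 0.00206) had the smallest p. With the offset the ribosomal median was 0.06 and the call ended (camera adjusted p = 0.971, the highest of 18 alternatives from 0.000838).

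Pathways around JAK2 and PIK3CA and the adhesion genes moved both ways in MDA-MB-231, and none of these 3 was called as a list. In JAK and STAT signalling 6 of 29 rose, 14 fell and 9 did not pass (median -0.32, or -0.44 with the offset; camera adjusted p = 0.557). The shared cytokine receptor IL6ST fell (-2.97, adjusted p = 1.85e-08) and the transcription factor STAT6 rose (1.49, adjusted p = 6.16e-08). Of 28 genes of PI3K, AKT and mTOR signalling 6 rose, 14 fell and 8 did not pass, or 8 and 15 adjusted over the list alone (median -0.28, camera adjusted p = 0.269). The PI3K list turned with the offset, with 13 rising, 7 falling and a median of 0.20, again without a call. RICTOR, which defines mTOR complex 2, fell (-3.38, adjusted p = 4.57e-09). Of 29 integrin and focal adhesion genes 8 rose, 13 fell and 8 did not pass (median -0.15, or -0.18 without 1 gene at the floor of 3 counts and -0.23 with the offset; camera adjusted p = 0.557). The laminin chain LAMA3 (-3.30, adjusted p = 1.87e-08) and the integrin ITGAV (-2.29, adjusted p = 3.51e-07) were among the falls. Apart from the PI3K list, the counts without the offset were the same adjusted over the list alone.

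Extract against control in HCC1937, at 66 µg/mL, raised MMP1, a collagenase, SNAI1, a repressor of epithelial genes, the xenobiotic-metabolising CYP1A1 and the stress factor ATF3. It lowered the antiviral genes SAMD9 and SAMD9L. MMP1 rose 58.8-fold, from 6.39 ± 0.263 to 376 ± 6.76 CPM (SD, n = 3; log2 fold change 5.88 ± 0.10, adjusted p = 3.65e-11). SNAI1 rose 18.1-fold, from 2.02 to 36.8 CPM (4.17 ± 0.16, adjusted p = 2.1e-09). CYP1A1 rose 15.4-fold, from 0.747 to 11.7 CPM (3.95 ± 0.20, adjusted p = 1e-08), and ATF3 11.5-fold, from 4.94 to 56.8 CPM (3.52 ± 0.09, adjusted p = 7.33e-10). HSPA6, an inducible HSP70, went from 0.0714 to 45.5 CPM (9.23 ± 0.27, adjusted p = 1.05e-09), with 6 reads over the 3 control libraries. PI3, the elastase inhibitor elafin, went from 71.9 to 964 CPM (3.74). FOSB of the AP-1 factors (3.69) and ARNT2, a partner of PAS-domain factors (3.56), completed the largest rises. SAMD9 went from 117 to 9.47 CPM (-3.62, adjusted p = 3.33e-08). Further large falls were IKZF2, a zinc finger factor of lymphocytes (-3.93), SAMD9L (-3.81), ZNF117 (-3.81), CCDC144A (-3.63), the transporter ABCA5 (-3.63) and ANKRD26 (-3.63). The proteoglycan lumican, LUM, fell too (-3.67 ± 0.39, and -4.37 without E31). The transcripts of these 8 falls are 3008 to 9350 nt long with 33.1% to 38.5% GC. With the offset all 16 genes kept their direction and call, the falls at -1.24 to -2.14, MMP1 at 6.14, HSPA6 at 8.44 and SNAI1 at 3.21. In all, 4625 genes rose, 5524 fell and 3984 did not pass, and 2325 rose and 3948 fell with a log2 fold change of at least 1. The median of all genes was -0.16, against -0.06 with DESeq2's size factors. With the offset 3055 rises and 3629 falls kept their direction and call, and 944 genes were called the opposite way.

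Interferon-induced genes fell in HCC1937: 23 of 28 fell, 1 rose and 4 did not pass, the same adjusted over the list alone. Interferon genes had a median of -1.76, or -1.88 with the offset (camera adjusted p = 9.73e-05; adjusted p = 0.0211 with an estimated correlation). IFIT1, which binds viral RNA, went from 57.4 to 6.45 CPM (-3.15 ± 0.11, adjusted p = 1.2e-09). The ubiquitin ligase family members HERC6 (-2.35, adjusted p = 3.46e-09) and HERC5 (-3.36, adjusted p = 4.73e-09) fell as well. Immediate early genes, which growth factors and stress switch on, rose for 17 of 25, fell for 3 and did not pass for 5, the same adjusted over the list alone. Immediate early genes had a median of 1.31, or 0.68 with the offset (camera adjusted p = 9.73e-05; adjusted p = 0.357 with an estimated correlation). Besides ATF3, the MAP kinase phosphatases DUSP6 (10.3 to 44.3 CPM, 2.10, adjusted p = 1.84e-09) and DUSP1 (17.5 to 48.9 CPM, 1.49, adjusted p = 2.11e-08) rose. Of 30 genes of hypoxia and glycolysis 23 rose, 5 fell and 2 did not pass, the same adjusted over the list alone. Hypoxia and glycolysis genes had a median of 1.27, or 0.59 with the offset (camera adjusted p = 9.73e-05; adjusted p = 0.0211 with an estimated correlation). With the offset and an estimated correlation together the interferon call held (adjusted p = 0.0038) and that of hypoxia and glycolysis did not (adjusted p = 0.277). ANGPTL4, an inhibitor of lipoprotein lipase, rose from 16.6 to 74.8 CPM (2.17, adjusted p = 8.95e-09). The glycolytic enzymes PFKP (1.47, adjusted p = 7.63e-09) and GPI (adjusted p = 1.61e-08) rose with it.

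Extracellular proteases and their regulators were higher in HCC1937 with extract, as were lysosomal and inflammatory genes. Of 24 protease genes 16 rose, 5 fell and 3 did not pass, the same adjusted over the list alone. Protease genes had a median of 0.79 (camera adjusted p = 0.00424; adjusted p = 0.142 with an estimated correlation). Besides MMP1, tissue plasminogen activator, PLAT, rose from 12.1 to 72.9 CPM (2.59, adjusted p = 4.12e-09) and cathepsin B, CTSB, from 256 to 939 CPM (1.87, adjusted p = 2.28e-09). With the offset the protease median was 0.20 and the call ended (camera adjusted p = 0.223, in a range of 5.86e-13 to 0.468 over 18 alternatives). Of 25 lysosome and autophagy genes 18 rose, 3 fell and 4 did not pass, the same adjusted over the list alone. Lysosome genes had a median of 0.56, or 0.41 with the offset (camera adjusted p = 0.000735; adjusted p = 0.142 with an estimated correlation). The sialidase NEU1 (1.36, adjusted p = 1.19e-08) and the lysosomal calcium channel MCOLN1 (1.23, adjusted p = 4.92e-08) rose next to CTSB. Of 23 NF-kB target and inflammation genes 13 rose, 2 fell and 8 did not pass, the same adjusted over the list alone. NF-kB genes had a median of 0.89, 0.90 without 1 gene that had too few reads for a fold and 0.62 with the offset (camera adjusted p = 0.00424; adjusted p = 0.0799 with an estimated correlation). Interleukin 1 beta, IL1B, rose from 6.30 to 26.7 CPM (2.08, adjusted p = 8.15e-08) and the NF-kB subunit RELB rose too (adjusted p = 1.3e-08). BIRC3, an inhibitor of apoptosis in the same list, fell (-3.08, adjusted p = 1.33e-08).

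Ribosomal and respiratory chain genes rose in HCC1937. Of 35 ribosomal proteins 30 rose, 0 fell and 5 did not pass, or 31 rose adjusted over the list alone. Their median was 1.25, against 0.33 with the offset (camera adjusted p = 8.04e-05; adjusted p = 0.719 with an estimated correlation). RPS3 (1.59, adjusted p = 2.02e-05), RPL8 (1.56, adjusted p = 2.58e-05) and RPL4 (1197 to 2567 CPM, adjusted p = 3.81e-05) had the smallest p. Of 29 nuclear genes of oxidative phosphorylation 24 rose, 1 fell and 4 did not pass, or 25 rose adjusted over the list alone. In this line respiratory genes had a median of 1.05, or 0.26 with the offset (camera adjusted p = 9.73e-05; adjusted p = 0.719 with an estimated correlation). CYC1 (1.90, adjusted p = 6.89e-08), SDHA of complex II (0.84, adjusted p = 3.61e-07) and ATP5F1B (1.27, adjusted p = 4.12e-07) were among the rises. ATF4 targets rose for 14 of 23, fell for 5 and did not pass for 4, the same adjusted over the list alone. ATF4 targets had a median of 0.49 (camera adjusted p = 0.0172; adjusted p = 0.124 with an estimated correlation), and TRIB3 (1.79, adjusted p = 1.84e-09) and PPP1R15A, which ends the stress block on translation (1.66, adjusted p = 4.12e-09), rose. S phase genes rose for 14 of 24, fell for 4 and did not pass for 6, the same adjusted over the list alone. In HCC1937 their median was 0.61 (camera adjusted p = 0.0219; adjusted p = 0.124 with an estimated correlation). Cyclin E1, CCNE1 (1.89, adjusted p = 8.55e-09), the helicase subunit MCM5 (1.47, adjusted p = 1.76e-08) and FEN1 (1.16, adjusted p = 5.46e-08) rose. With the offset both calls ended (ATF4 targets median 0.10, camera adjusted p = 0.223; S phase median 0.39, camera adjusted p = 0.0986). Over 18 alternatives the adjusted p reached from 5.86e-13 to 0.427 for ATF4 targets and from 4.16e-11 to 0.124 for S phase.

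Many common reference genes were not stable relative to the other genes. In HCC1937 10 of 14 housekeeping genes rose, 1 fell and 3 did not pass, the same adjusted over the list alone. Housekeeping genes had a median of 0.83, or 0.44 with the offset (camera adjusted p = 0.0119; adjusted p = 0.561 with an estimated correlation). The glycolytic PGK1 (1.29, adjusted p = 3.24e-08), GAPDH (1.34), and ACTB (1.15) rose. The transferrin receptor TFRC fell (-0.58, but 0.64 with the offset). In MDA-MB-231 7 of 14 rose, 2 fell and 5 did not pass, and the list was not called (median 0.30, or 0.32 with the offset; camera adjusted p = 0.172). GAPDH (0.82, or 0.46 without E7, but -0.04 with the offset), ACTB (1.36) and TBP (1.04) rose there, while YWHAZ (-0.27, but 0.77 with the offset) fell. PGK1 (0.031), HPRT1, B2M, TFRC and PPIA did not pass, and all of these but PPIA passed with the offset.

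Lists around JAK2 and PIK3CA, adhesion and mitosis moved both ways in HCC1937 and were not called. Of 25 mitosis genes 7 rose, 15 fell and 3 did not pass (median -1.66, camera adjusted p = 0.0712). CENPF (-3.40, adjusted p = 1.1e-09) and the kinesin KIF23 (-2.24, adjusted p = 1.1e-09) were among the falls. This list was called with the offset (median -0.77, adjusted p = 0.0254) and without E7 (adjusted p = 0.0364), in a range of 1.45e-10 to 0.165 over 18 alternatives. It was not called with an estimated correlation (adjusted p = 0.165, or 0.378 with the offset as well). E7, a library of the other line, enters this test mainly through the spread shared by all 4 groups. In JAK and STAT signalling 9 of 29 rose, 11 fell and 9 did not pass. The median was 0.21 and the mean -0.26, of opposite sign (camera adjusted p = 0.918), with the cytokine IL11 rising (1.76, adjusted p = 1.5e-08) and PIAS1, a SUMO ligase, falling (-1.99, adjusted p = 1.66e-08). With the offset 9 rose and 14 fell, and the median turned to -0.17, again without a call. Of 28 PI3K, AKT and mTOR genes 7 rose, 14 fell and 7 did not pass (median -0.49, camera adjusted p = 0.316). With the offset 11 rose and 10 fell, with a median of -0.07, so the excess of falls was gone. The kinase SGK1 rose (2.55, adjusted p = 4.83e-09). Of 29 integrin and focal adhesion genes 14 rose, 11 fell and 4 did not pass (median 0.45 and mean -0.03, of opposite sign; camera adjusted p = 0.472). Zyxin, ZYX, rose (1.72, adjusted p = 5.74e-09) and the integrin ITGB8 fell (-2.92, adjusted p = 1.29e-08). With the offset this list was called (median 0.38, adjusted p = 0.0476, in a range of 1.17e-14 to 0.866 over 18 alternatives, the highest with an estimated correlation), but not with the offset and an estimated correlation together (adjusted p = 0.378). All counts without the offset were the same adjusted over the list alone.

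**Figure D3:**
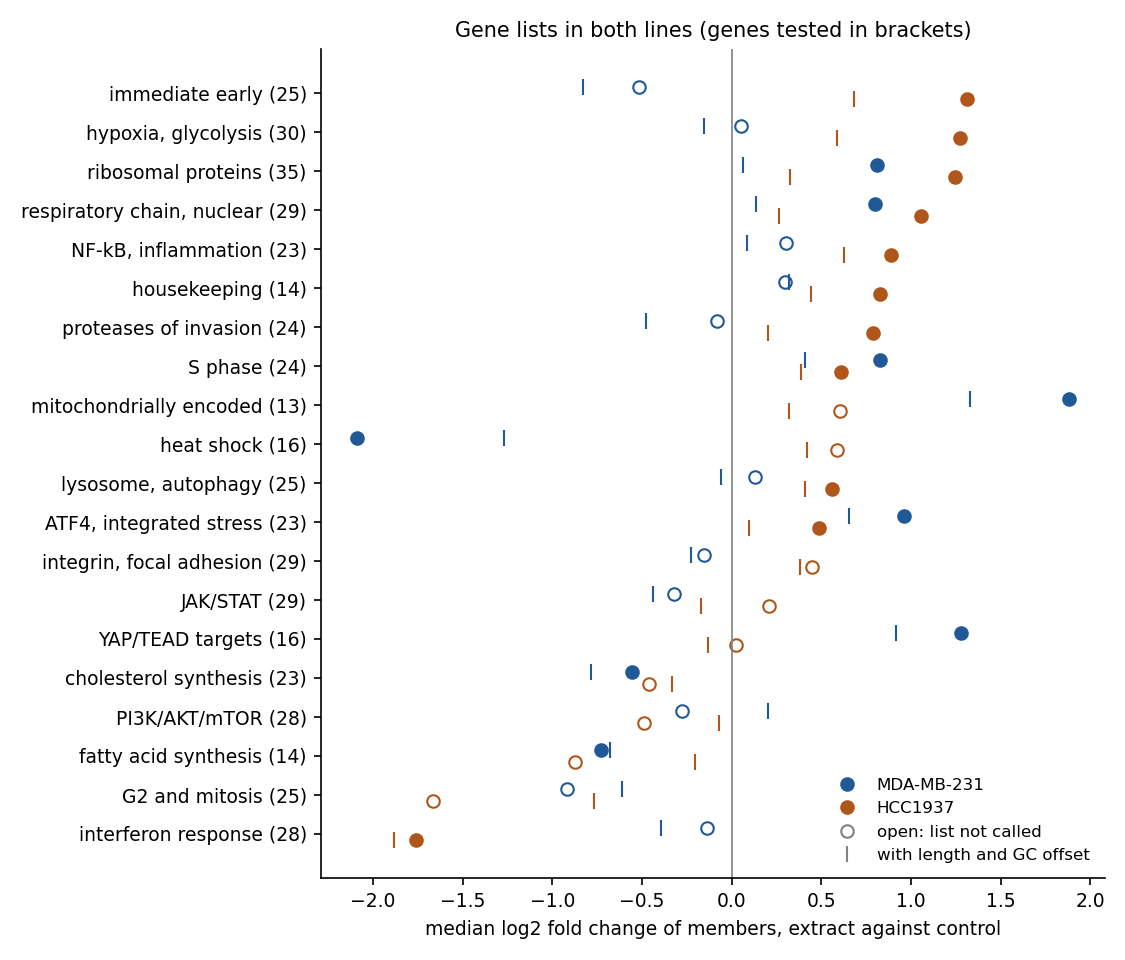
Median log2 fold change with extract (horizontal axis) of 20 gene lists in MDA-MB-231 and HCC1937, filled where camera at the preset correlation called the list, open where not, and with a tick at the median with the length and GC offset. Heat shock chaperones in MDA-MB-231 (-2.09) and interferon-induced genes in HCC1937 (-1.76) have the lowest medians of the called lists.

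The extract effects of both lines overlapped far more than their margins give. Of the genes that rose, 3428 were shared (1527 expected, odds ratio 19.1), and of those that fell, 3574 (1812 expected, odds ratio 13). ROCK1, ROCK2, PIK3CA, JAK2, CENPF and ANKRD26 were among the shared falls, and TRIB3, FEN1, CYC1 and RPL8 among the shared rises. In opposite directions, 327 genes rose in MDA-MB-231 and fell in HCC1937, and 224 did the reverse. With the offset 2948 rises (1409 expected, odds ratio 10.5) and 3026 falls (1682 expected, odds ratio 6.60) were shared. Opposite calls were then more frequent, with 403 genes higher in MDA-MB-231 and lower in HCC1937, and 450 the reverse. Across genes, which are not independent replicates, the log2 fold changes of the lines had a Pearson correlation of 0.65 and a Spearman correlation of 0.70, and 0.50 and 0.58 with the offset.

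The difference of the extract effect between the lines asks which genes responded unlike each other, although concentration and medium differed as well. Heat shock chaperones differed in many members. In HCC1937 7 of 16 rose, 4 fell and 5 did not pass with extract, and the list was not called (median 0.59, or 0.42 with the offset; camera adjusted p = 0.295). HSPA8, the constitutive HSP70, went from 4775 to 1158 CPM in MDA-MB-231 and from 834 to 2913 CPM in HCC1937 (difference 3.85, adjusted p = 1.91e-09), and DNAJB1 differed by 4.40 (adjusted p = 2.61e-09). HSPA6 went from 80.1 to 11.5 CPM in MDA-MB-231, against its rise in HCC1937 (12.03 ± 0.31, adjusted p = 1.9e-09). HSPA1B, an inducible HSP70, went from 4375 to 291 CPM against 193 to 651 CPM (5.66 ± 0.34, adjusted p = 6.55e-07). RND1 went from 12.7 to 3.54 CPM against 0.513 to 7.96 CPM (5.78 ± 0.31, adjusted p = 3.58e-07). TENT5C, a poly-A polymerase, went from 20.8 to 3.14 CPM against 0.573 to 3.85 CPM (5.46 ± 0.30, adjusted p = 4.35e-07). The largest differences the other way were the tumour antigens MAGEA12 (-6.57, adjusted p = 0.00556) and MAGEA3 (-6.16, adjusted p = 0.00134), the ribosomal protein copy RPL39L (-6.48, adjusted p = 0.0399) and the kinase CAMK1 (-5.89, adjusted p = 0.0247). In HCC1937 these 4 rest on 13 reads for MAGEA12, 13 for MAGEA3, 18 for RPL39L and 13 for CAMK1 over the controls and 0 with extract. That is at least 3.86-fold, 3.97-fold, 5.39-fold and 4.10-fold lower, and the fitted differences are no bound.

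Among the title genes the fall was smaller in HCC1937 for ROCK1 (difference 1.08, adjusted p = 0.00642) and PIK3CA (0.86, adjusted p = 0.00925). ROCK2 (0.64, adjusted p = 0.0423) lost its call in 10 of 20 alternatives, 8 of them with 1 library left out (adjusted p = 0.0550 to 0.0983), and for JAK2 no difference was detected (-0.35, adjusted p = 0.574). In all, 1630 genes had a higher and 2909 a lower effect in HCC1937, and 9594 did not pass. These counts were 3554 and 4780 without E7. With DESeq2's size factors they were 2042 and 2315, which moved the share of higher calls from 35.9% to 46.9% and the median of all genes from -0.16 to -0.05. The call of RPL39L was lost on leaving out any of 8 of the 12 libraries (adjusted p = 0.0537 to 0.103) and that of CAMK1 without E25 (-4.38, adjusted p = 0.0645) or E33 (adjusted p = 0.0509). Without E27 the difference was -5.10 for MAGEA12 and -5.90 for RPL39L.

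Of the 38 lists, 15 were called for this difference, and 5 of them with an estimated correlation. Of 16 chaperones 11 had a higher effect in HCC1937, none a lower one and 5 did not pass, or 12 and 1 adjusted over the list alone. Chaperones differed by a median of 1.44 (camera adjusted p = 6.66e-10; adjusted p = 0.00217 with an estimated correlation), HSPH1 among them (1.98, adjusted p = 4.81e-07), which fell in HCC1937 as well, but less (242 to 85.7 CPM, -1.50, or -0.04 with the offset and not called). Hypoxia and glycolysis genes were higher for 20 of 30, lower for 1 and did not pass for 9, or 22 and 1 adjusted over the list alone. Their median difference was 0.83 (camera adjusted p = 2.91e-09; adjusted p = 0.00217 with an estimated correlation). The stress gene NDRG1 (3.38, adjusted p = 2.72e-06), the peptide hormone ADM (2.81, adjusted p = 9.83e-08) and PGK1 (1.26, adjusted p = 8.92e-06) had a higher effect. Interferon genes were lower for 19 of 28, higher for 2 and did not pass for 7, or 21 and 2 adjusted over the list alone. Interferon genes differed by a median of -1.65 (camera adjusted p = 2.64e-06; adjusted p = 0.00518 with an estimated correlation), with IFIT3 lower (-3.27, adjusted p = 3.5e-07). Protease genes were higher for 11 of 24, lower for 3 and did not pass for 10, the same adjusted over the list alone. Protease genes differed by a median of 0.74 (camera adjusted p = 1.6e-05; adjusted p = 0.0353 with an estimated correlation), with MMP1 (4.70), PLAT (2.35) and CTSB (1.73) higher. NF-kB genes were higher for 11 of 23, lower for 2 and did not pass for 10, the same adjusted over the list alone. NF-kB genes differed by a median of 0.88 (camera adjusted p = 0.000348; adjusted p = 0.0213 with an estimated correlation), with IL1B (2.42), IER3 (2.03) and the superoxide dismutase SOD2 (0.94) higher.

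Immediate early genes were higher for 15 of 25, lower for 3 and did not pass for 7, or 16 and 3 adjusted over the list alone. Immediate early genes differed by a median of 1.47 (camera adjusted p = 1.51e-08; adjusted p = 0.133 with an estimated correlation). FOS, a subunit of AP-1, went from 268 to 25.9 CPM in MDA-MB-231 and from 30.7 to 76.1 CPM in HCC1937 (4.68 ± 0.14, adjusted p = 1.9e-09). Replication histones were higher for 9 of 20, lower for 1 and did not pass for 10, the same adjusted over the list alone. Per the labels RNA was captured by its poly-A tail, so histone counts here and below may not follow histone transcripts as a whole. Histones differed by a median of 1.79 (camera adjusted p = 0.000179; adjusted p = 0.248 with an estimated correlation), with H2BC11 (4.03, adjusted p = 1.57e-06) and H2BC5 (2.21, adjusted p = 0.00033) higher. With the offset these 7 medians were 1.60 for chaperones, 0.73 for hypoxia and glycolysis, -1.51 for interferon, 0.70 for proteases, 1.06 for NF-kB, 1.56 for immediate early genes and 1.85 for histones. Without E7 they were 1.46, 1.01, -1.75, 0.50, 0.94, 1.44 and 1.83. A few members have too few reads in 1 line for a fold, or none in a group. Without these the medians were 2.21 over 15 histones, 0.75 over 22 NF-kB genes, -1.67 over 25 interferon genes and 0.74 over 22 protease genes, and camera called all 4 lists (adjusted p of at most 0.000408). With the offset and an estimated correlation together, the calls of chaperones (adjusted p = 0.0122), hypoxia and glycolysis (adjusted p = 0.00911) and interferon genes (adjusted p = 0.00911) held, and those of proteases (adjusted p = 0.208) and NF-kB genes (adjusted p = 0.0871) did not.

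HCC1937 controls against MDA-MB-231 controls describes the lines before treatment, with medium confounded. HCC1937 was the more epithelial line: all 22 epithelial genes were higher, also adjusted over the list alone. Epithelial genes had a median of 3.97 (camera adjusted p = 3.15e-09; adjusted p = 0.0171 with an estimated correlation). MAL2, a trafficking protein of epithelia, was at 1119 CPM against 0.882 (10.31 ± 0.21, adjusted p = 1.03e-11), and P-cadherin, CDH3 (7.28), and the splicing regulator ESRP1 (6.66) were higher. Basal keratinocyte genes were higher for 13 of 14 and lower for 1, also adjusted over the list alone. Basal genes had a median of 8.89, or 6.44 with genes at 0 set at their bound (camera adjusted p = 2.11e-06; adjusted p = 0.0205 with an estimated correlation). KRT15 (3.92) was among them, as was KRT17, with 6 reads over the MDA-MB-231 controls and 37610 over the HCC1937 controls. The tumour suppressor CDKN2A, E-cadherin CDH1 and the basal keratin KRT5 had no reads in MDA-MB-231 controls and were at least 3190-fold, 3690-fold and 1170-fold higher in HCC1937. Mesenchymal genes were lower in HCC1937 for 14 of 19 and higher for 5, also adjusted over the list alone. Mesenchymal genes had a median of -2.33 (camera adjusted p = 0.0134; adjusted p = 0.0679 with an estimated correlation). The filament vimentin, VIM, was at 13.9 CPM against 3736 (-8.07 ± 0.25), and the matricellular genes CCN1 (-4.29) and CCN2 (-3.74) were lower.

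Chaperones were lower in HCC1937 controls for 14 of 16, higher for 1 and did not pass for 1 (median -1.44, camera adjusted p = 0.000476). NF-kB genes were lower for 19 of 23, higher for 3 and did not pass for 1 (median -2.85, camera adjusted p = 7.84e-05). Interferon genes were higher for 23 of 28, lower for 4 and did not pass for 1 (median 1.61, camera adjusted p = 0.000512). These counts were the same adjusted over the list alone, and all 3 calls held with an estimated correlation (adjusted p = 0.0205 to 0.0242). By their medians immediate early (-2.45), hypoxia and glycolysis (-0.97) and protease genes (-0.28) were lower in HCC1937 controls as well. Replication histones were higher (0.73). Apart from histones, these medians have the opposite sign of the median difference of the extract effect. Both comparisons use these controls, with opposite sign. Whether the differences follow the level in controls was not tested. In all, 5466 genes were higher and 5181 lower in HCC1937, and 3486 did not pass. In HCC1937 controls, 26 genes abundant in MDA-MB-231 and near 0 in HCC1937 extract libraries lay at a median of 0.357% of their MDA-MB-231 control level. Values this far below the other line, VIM among them, are near that background.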

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

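Of the tests in this part, the splits of the libraries were planned, and those on carried-over reads were chosen after the result was seen. All results here come from the test of the difference of the extract effect between the lines (HCC1937 minus MDA-MB-231), in which line, concentration and medium are confounded, so a biological difference between the lines stays untested. The effect was higher in HCC1937 for 1630 genes and lower for 2909, and 551 genes were called in opposite directions in the lines, each with a called difference. Of 100 drawn splits, which exchange libraries between the lines within controls and within extract, 3 gave at least as many genes as the 4539 of the real one, the real one included. The highest other split gave 11392. It kept the lines apart but joined the MDA-MB-231 controls with the HCC1937 extract libraries, so it follows the structure of the lines. Of the 98 splits that mixed the lines, 75 gave no gene and the highest gave 4606. For lists, 1 of 100 splits, the real one, gave 15 calls, and the highest other gave 13. Mixing the lines adds their difference to the spread within groups, so these splits are not like the real one. Only 2 of the 100, the real one included, kept the lines apart, too few for a share under 0.05 among like splits.

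Among single genes the difference was 12.03 for HSPA6, 5.78 for RND1, 5.66 for HSPA1B and 5.46 for TENT5C, all lower with extract in MDA-MB-231 and higher in HCC1937. It was -6.57 for MAGEA12, -6.48 for RPL39L, -6.16 for MAGEA3 and -5.89 for CAMK1, which rose in MDA-MB-231 and had no reads in HCC1937 extract libraries.

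Lists with a higher effect in HCC1937 had median differences of 1.79 for replication histones (2.21 without 5 genes that had too few reads in MDA-MB-231 for a fold), 1.47 for immediate early genes, 1.44 for chaperones, 0.88 for NF-kB (0.75 without 1 such gene, which had too few in HCC1937), 0.83 for hypoxia and glycolysis and 0.74 for proteases. Interferon genes had a median of -1.65. Replication histones (adjusted p = 0.248) and immediate early genes (adjusted p = 0.133) lost their call with an estimated correlation, and so did all further called lists. Integrin and focal adhesion genes differed by a median of 0.46, or 0.56 without 1 gene with too few reads for a fold (camera adjusted p = 0.0303; adjusted p = 0.834 with an estimated correlation), with LAMA3 (3.17) and the integrin ITGB4 (2.37) higher. Lysosome genes differed by 0.39 (camera adjusted p = 0.00127; adjusted p = 0.133 with an estimated correlation). Ribosomal proteins differed by 0.34 (camera adjusted p = 0.00611; adjusted p = 0.834 with an estimated correlation), where 1 of 35 passed, and by 0.94 without E7, with the call lost without E8 (adjusted p = 0.0956) or E9 (adjusted p = 0.0887). The gene that passed, RPL4 (edgeR adjusted p = 0.0320), lost its call on leaving out any library other than E7 (adjusted p = 0.0572 to 0.0695). RPS3 did not pass with all libraries (edgeR adjusted p = 0.0730) but did without E7 (adjusted p = 4.29e-17). The unfolded protein response differed by 0.25 (camera adjusted p = 0.0345; adjusted p = 0.133 with an estimated correlation), although XBP1, its transcription factor, was lower (-1.48) and HSPA5, its main chaperone, higher (1.39). Antigen presentation differed by 0.20 (camera adjusted p = 0.047; adjusted p = 0.477 with an estimated correlation), with HLA-E (1.13) and HLA-B (0.74) higher. Respiratory genes differed by 0.14 (camera adjusted p = 0.0234; adjusted p = 0.836 with an estimated correlation), and by 0.76 without E7, with the call lost without E8 (adjusted p = 0.181) or E9 (adjusted p = 0.173). Cholesterol genes had a median of -0.015 but a mean of 0.19, of opposite sign, and camera called them higher (adjusted p = 0.047; adjusted p = 0.133 with an estimated correlation). The cholesterol call was also lost on leaving out any of 8 libraries (adjusted p = 0.0503 to 0.0785) and that of antigen presentation on leaving out any of 6 (0.0505 to 0.121). Mitochondrially encoded genes differed by -1.14 (camera adjusted p = 0.0345; adjusted p = 0.834 with an estimated correlation), and by -0.67 without E7. With the offset the calls of antigen presentation, respiratory and cholesterol genes ended.

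Transcripts typical of MDA-MB-231 were present at trace levels in HCC1937 controls and fewer in HCC1937 extract libraries, among them MAGEA12, MAGEA3, RPL39L and CAMK1. Over 26 genes abundant in MDA-MB-231 and near 0 in HCC1937 extract libraries, 100% had reads in HCC1937 controls, at 1 ratio: the quartiles of their level relative to MDA-MB-231 lay 1.84-fold apart (0.248% to 0.456%). Low expression of each gene in HCC1937 that the extract turned off would have spread these ratios, so the values argue against it, and reads or RNA carried over from MDA-MB-231 may account for most of them. Of 3948 genes at 50 CPM or more in MDA-MB-231 controls, 9 lay under 0.248% in HCC1937 controls, the lowest SLC2A3 (0.0834%, 38 reads) and HSPA6 (0.0891%, 6 reads). For 1 of them, SLC2A3, the reads were fewer than 0.248% would bring (111 expected, Poisson adjusted p = 3.6e-12), which argues against carry-over at 1 ratio from a source with the levels of these controls as the whole cause. SLC2A3 was at 528 CPM in these controls and 124 CPM in MDA-MB-231 extract libraries, so a source with other levels is not argued against. In the other direction, 49.1% of 55 genes typical of HCC1937 had reads in MDA-MB-231 extract libraries, with a median of 0, which argues against carry-over there. Where the carried-over reads came from, cultures, libraries or sequencing, stays open.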

How the results depend on the processing

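In this part the counts without genes at trace level, the offset for the overlap and the offset with E7 left out were chosen after the data were seen. No paired analysis was possible because the groups compared share no replicate numbers. Scaling by DESeq2's size factors or the upper quartile, DESeq2, limma-voom and either count filter kept the direction of all named genes that had a call, and the call of 213 to 215 of 215 values, RGPD6 among the exceptions. Without a call, direction changed for PGK1 in MDA-MB-231 with the upper quartile (-0.031) and the filter of 50 counts (-0.014), and in HCC1937 for HPRT1 (0.056) and B2M (0.044) with DESeq2's size factors. In the counts that follow, a value without a call before and after counts as kept whatever its sign. With the offset 190 of 215 kept both, and 2548 of 2580 values on leaving out 1 library. Of 58 list results, 58 kept both with DESeq2's size factors, 47 with the offset, 30 with an estimated correlation and 674 of 696 on leaving out 1 library.

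A log2 fold change of at least 1 left 2112 higher and 2968 lower genes in MDA-MB-231, 2325 higher in HCC1937, 741 and 1305 for the difference, and 3314 and 3224 between the controls, by the construction of that threshold. For the difference, the offset gave 2597 higher genes, and 3704 without E7. An estimated correlation left 3 lists in MDA-MB-231, 2 in HCC1937 and 5 for the difference. Directional fry called 29, 31 and 32 (MDA-MB-231, HCC1937 and controls) and mixed fry 38, 38, 36 for the difference and 37 for the controls, since fry does not compare a list with other genes. It called JAK and STAT genes in HCC1937 lower, against a median of 0.21. Among the 500 genes with the smallest p per line and direction, 231 were shared higher and 333 lower, as fewer genes were compared. PIK3CA in HCC1937 was at -0.12 with the offset, with and without E7. ROCK2 lost its call for the difference with limma-voom (0.64) and with no count filter (0.64), and ribosomal proteins in MDA-MB-231 were at -0.14 with the offset without E7, called neither way (adjusted p = 0.108, in a range of 0.000838 to 0.971). For these changes the cause was not tested.

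Direction turned, with a call before or after, with the offset, and in the second value with E7 left out too, in MDA-MB-231 for VIM (-0.51, -0.70), GAPDH (-0.039, -0.24), YWHAZ (0.77, 0.73), SDHA (-0.31, -0.31), GUSB (-0.43, -0.41) and SLC7A11 (0.20, 0.29). With both settings together it turned for KRT19 (-1.33), PPIA (-0.075) and RPLP0 (-0.13) as well. Without E7 alone it turned for VIM (-0.095, in a range up to 0.34 without E8) and B2M (-0.11), and with no call before or after for KRT19 (-0.62) and HPRT1 (-0.019). KRT19 turned without a call with the offset alone as well (-0.90), and without E3 (-0.40). In HCC1937 it turned for CDKN2A (-0.094, -0.094), KRT5 (-0.44, -0.44), HPRT1 (0.43, 0.43), YWHAZ (1.25, 1.25), GUSB (-0.40, -0.40), B2M (0.70, 0.70), TFRC (0.64, 0.64) and SLC7A11 (0.14, 0.14), and with both settings for KRT19 (-0.57), which had no call with the offset alone (-0.57). Among lists without a call the median turned with the offset for PI3K, AKT and mTOR genes in MDA-MB-231 (0.20, 0.23) and for JAK and STAT genes in HCC1937 (-0.17, -0.17). The offset takes out the trend with length and GC, and what else set these genes was not tested.

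Leaving out 1 library gave 4211 to 5363 higher and 4256 to 5349 lower genes in MDA-MB-231, 4255 to 5471 and 5149 to 6215 in HCC1937, 1340 to 3554 and 2344 to 4780 for the difference, and 5144 to 6239 and 4831 to 6231 between the controls, each highest without E7. E7 also raised the spread behind comparisons it is not part of, since all groups share an estimate of it. The MDA-MB-231 extract group had a biological coefficient of variation of 0.296, against 0.0409 to 0.0449 in the other groups. So the shared estimate may understate the SE and p-values of comparisons with this group. Shared rises were 3191 to 4080 and shared falls 3326 to 4084. ROCK2's difference was 0.50 to 0.77. Depth limits JAK2 (38 reads in HCC1937 extract libraries) and genes at 0 in a group.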

Other observations

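In this part the splits of the libraries and the tests of gene lists were chosen beforehand, and the tests on the trend with length and GC, the title genes and E7 after the result was seen. Genes of other responses moved in both lines without a call for their list. Of 23 targets of NRF2, the factor of the oxidative stress response, 11 rose, 3 fell and 9 did not pass in MDA-MB-231 (median 0.33, or 0.20 with the offset; camera adjusted p = 0.351). In HCC1937 11 rose, 8 fell and 4 did not pass (median 0.38, or 0.26 with the offset; camera adjusted p = 0.273). OSGIN1, an oxidative stress growth inhibitor, rose in HCC1937 from 3.19 to 25.6 CPM (3.00, adjusted p = 7.85e-09), and the exporter ABCC3 fell in MDA-MB-231 (-1.76, adjusted p = 7.8e-08). Of 28 regulators of apoptosis 12 rose, 7 fell and 9 did not pass in MDA-MB-231, or 12 and 8 adjusted over the list alone (median 0.09, or 0.13 without 1 gene at the floor and 0.215 with the offset; camera adjusted p = 0.557). In HCC1937 13 rose, 11 fell and 4 did not pass (median 0.13, or 0.165 with the offset; camera adjusted p = 0.594). The apoptosis inhibitors BIRC3 (-4.23) and BIRC2 (-2.02) fell in MDA-MB-231, and in HCC1937 BIRC2 fell (-2.51, adjusted p = 1.84e-09) while BAK1, which permeabilises mitochondria, rose (1.77, adjusted p = 2.46e-09).

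Kalanchoe plants are known for bufadienolides, steroids that block the sodium pump, and 17 genes of sodium and calcium transport and osmotic balance were tested as a list. In MDA-MB-231 5 rose, 7 fell and 5 did not pass (median 0.00 with and without the offset, or -0.24 with 2 genes without reads left out and 1 at its bound; camera adjusted p = 0.739), and in HCC1937 6 rose, 7 fell and 4 did not pass (median -0.23, or -0.21 with the offset; camera adjusted p = 0.953). The calcium pump ATP2B1 fell in both lines (-2.68 and -2.72). The phosphate carrier SLC20A1 fell in MDA-MB-231 (-2.29, adjusted p = 5.81e-08) and the chloride carrier SLC12A2 in HCC1937 (-1.88, adjusted p = 1.2e-08). Markers of other cell types were not called as lists in either line: of 5 fibroblast genes 0 rose and 1 fell in MDA-MB-231 and 0 rose and 3 fell in HCC1937. Of 5 endothelial genes 1 rose and 1 fell in MDA-MB-231 and 1 rose and 2 fell in HCC1937. Of 11 luminal genes 4 rose and 4 fell, and 5 rose and 5 fell. These counts of NRF2, ion transport and cell type genes were the same adjusted over the list alone.

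Long or GC-poor transcripts fell with extract in both lines. Across genes, which are not independent replicates, the fold change followed GC content at a given length (partial Spearman rho of at least 0.490 in both lines) and length at a given GC content (-0.356 or further from 0). So neither shorter RNA molecules nor uneven recovery of GC-poor sequence accounts for it alone. Genomic span had a rho of -0.464 in MDA-MB-231 and -0.446 in HCC1937 on its own. At a given transcript length, GC content and exon number its partial rho was -0.0678 and -0.0178, among 7 relations computed per line. So little relation to span was left beyond these measures. Slower transcription of genes with a long span, where span goes with them, cannot be told apart. At a given length, GC content and span, genes with more exons had lower fold changes (partial rho of -0.182 in MDA-MB-231 and -0.177 in HCC1937). The offset and the choice of the 200 nearest genes use length and GC only, so this relation was not taken out. RNA quality or library preparation that differed between extract and control libraries, acting through length and GC content together, may account for part or all of the trend. Whatever its cause, the trend held 43.9% of the variance of fold changes in MDA-MB-231 and 54.7% in HCC1937. Such a technical cause cannot be told apart from an effect of the extract on such transcripts, since every extract library is compared with control libraries and the labels name no preparation batch. With the offset the title genes other than PIK3CA in HCC1937 stayed at -1.16 or lower (PIK3CA in MDA-MB-231 at -0.98 with E7 left out too), so the fitted trend alone does not give their whole fall. This does not set them apart from the scatter of like transcripts. With the offset 4521 genes rose and 4667 fell in MDA-MB-231, and 4405 and 5093 in HCC1937, so most genes were still called. Among the 200 genes nearest in length and GC, ROCK1 and ROCK2 stood at percentile 6 or lower. JAK2 stood at 21 in MDA-MB-231 and 10 in HCC1937, and PIK3CA at 13 in MDA-MB-231. PIK3CA in HCC1937 went from -2.51 ± 0.15 to -0.12 ± 0.12 and lost its call because its size fell to that of like transcripts, which the trend may explain.

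E7 stood apart from E8 and E9, with 1699 of 10434 genes at least 1 away from their mean on the log2 scale. At a given GC content, E7 was lower for longer transcripts across genes (partial Spearman rho of -0.689), as shorter RNA molecules in E7 may give. At a given length it was also lower for transcripts rich in GC (partial rho of -0.308), so shorter molecules do not account for it alone. Whether E7 also responded more strongly to the extract stays open. At a given length and GC content, E7 against E9 followed the effect in E8 with a partial rho of 0.0987, and E7 against E8 the effect in E9 with 0.0879, too near the bound of 0.1 to decide. E7 against both followed the effect in HCC1937 with 0.206. A library of the other line is argued against, since all 8 genes that tell the lines apart lay nearer MDA-MB-231. A degraded sample or a fault in preparation stays open too, as the labels give no RNA quality.

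Extract against control gave 9303 called genes in MDA-MB-231 (1 of 10 splits gave as many, the real one; highest other 0) and 10149 in HCC1937 (1 of 10; highest other 0). The controls of the lines gave 10647 (1 of 10; highest other 0). For lists the values were 9 against 8 (1 of 10), 11 against 12 (3 of 10) and 9 against 9 (3 of 10). With 3 libraries per group, 10 splits are too few for a share under 0.05.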
